A study of Rattus norvegicus with 10 samples.

How the data were processed

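RNA sequencing was used to measure polyadenylated RNA in the supraoptic nucleus (SON) of Wistar Han rats, a hypothalamic nucleus of magnocellular neurones that make vasopressin and oxytocin. Per the labels' protocols, cages were allotted at random to free access to water (euhydrated) or to 72 h without water (dehydrated), and both SONs were punched with a 1 mm corer from 12 frozen slices. Libraries were made with a stranded mRNA kit, per the labels' protocols. There were 5 samples per group. Nothing in the labels says that each sample was a separate animal, so p-values measure the spread between these samples, which may be partly technical. Water access was allotted by cage, and cage was not part of the model.

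The authors deposited raw read counts per Ensembl gene for each sample, with no normalisation, as whole numbers with a different total in each sample. Per the submitters' processing notes, CASAVA, FastQC, STAR, featureCounts and DESeq2 1.28.1 were used. The genome build, the annotation release and the strand setting of the counting are not given in the sources used here, so no coordinates are printed and overlapping, antisense or near-identical genes (such as the hemoglobin genes and the ribosomal protein genes with their pseudogenes) are uncertain. The authors also deposited a table of their own comparison, with log2 fold changes and standard errors, p-values and adjusted p-values, a Wald statistic (a score) and normalised counts per sample (a signal), per the file headers. Checked against the counts, 100% of these normalised values equalled the count divided by 1 size factor per sample, within 1% or 0.1. Gene symbols came from the authors' deposited table, which pairs them with the Ensembl identifiers; 407 identifiers had no symbol. A RefSeq gene table of the assembly GRCr8 was used only to match other names of list members.

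Columns of the count table were tied to samples by their names. The dehydrated numbers matched the labels, as did euhydrated 1 and 2; the other 3 euhydrated columns carry numbers that the labels give in 2 differing ways, so these were tied to the group only. Libraries are named by the number in the column. Counts of every pair of libraries within a group differed by more than sampling noise (chi-square per degree of freedom 4.88 to 12.2 over genes with at least 20 counts), so no library was counted as a duplicate.

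Genes were kept with edgeR's filterByExpr, which left 15311 of 32402 listed genes, and scaled by TMM factors. The groups were compared with edgeR 4.0.16 (glmQLFit and glmQLFTest, robust) in R 4.3.3 with no covariate, and p-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. "edgeR adjusted p" means this value throughout. Levels are CPM (counts scaled by library total) after TMM scaling, and log2 CPM used a prior count of 2. Fold changes are dehydrated over euhydrated.

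Before the data were examined, 31 gene lists (17 of processes, 14 of cell types) were fixed from textbook knowledge, with 717 memberships, of which 697 were matched and 665 tested. Unmatched members were not analysed here. Each list was described by the number of members that rose, fell or did not pass the threshold, over all genes tested and adjusted over the list alone. It was then tested against all other genes with camera in limma 3.58.1, with a preset inter-gene correlation of 0.01 and with an estimated one, adjusted over the 31 lists. The fry test, which asks whether a list's genes move on balance 1 way without comparing them with other genes, was an alternative. Shares of counts and mean log2 CPM of cell type markers were compared by exact two-sided permutation tests over the 252 labellings of the 10 libraries, whose smallest possible p is 0.00794. The rule for named genes was also fixed then. It takes 12 genes chosen for their known roles in the SON, the 8 largest rises and 8 largest falls among genes with a symbol past the threshold with a mean CPM of at least 5 and no overlap between the groups, the 4 smallest p-values in each direction among genes not yet named under the same conditions, and up to 4 members of each list, those past the threshold with the largest changes or, where none passed, the 2 with the highest mean CPM. Uncharacterised loci were left out of the middle parts of the rule.

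The alternatives were DESeq2 size factors, library totals without TMM factors, Avp and Oxt left out of the counts, 2 other filters on low counts, DESeq2 1.42.0, limma-voom, blocks by replicate number, a surrogate variable from sva 3.50.0, marker levels as covariates, stricter thresholds, and each library left out in turn. The block by column number and the erythrocyte covariate were added after the data were seen.

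The edgeR test was tested on simulated data drawn from the real means, dispersions and library totals of this comparison (15317 genes passed its filter), with 50 genes changed at each of 4 folds. It recovered 56% of genes changed 1.25-fold, 82% changed 1.5-fold, 84% changed 2-fold and 98% changed 4-fold. Of its 166 calls, 6 were false.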

Results

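Each of the 10 libraries held 24268398 to 28491926 counts assigned to genes, and 18709 to 18969 genes had at least 1 count in a library. Mitochondrially encoded genes took 10.9% to 13.4% of the counts. Pearson correlations of log2 CPM across genes were 0.991 to 0.993 within groups and 0.988 to 0.990 between them (genes are not independent replicates). The first principal component held 25.6% of the variance, and all 5 dehydrated libraries lay on the other side of it from all 5 euhydrated libraries. The second held 12.6%.

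The comparison of dehydrated with euhydrated samples asked which SON transcripts change after 72 h without drinking water. Several genes tied to magnocellular neurones rose. Creb3l1 (ENSRNOG00000005413), a transcription factor known to act on the vasopressin gene, rose 3.76-fold, from 21.1 ± 3.40 to 79.2 ± 10.5 CPM (SD, n = 5 per group; edgeR adjusted p = 8.06e-06). Caprin2, an RNA-binding protein, rose 3.50-fold, from 92.5 ± 13.1 to 324 ± 27.4 CPM (edgeR adjusted p = 6.36e-06), and Slc12a1, a sodium-potassium-chloride cotransporter best known from the kidney, rose 3.45-fold, from 8.24 ± 1.59 to 28.5 ± 2.79 CPM (edgeR adjusted p = 8.07e-07). Pdyn, which encodes prodynorphin, rose 2.04-fold to 1012 ± 65.5 CPM (edgeR adjusted p = 0.000261).

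The vasopressin transcript itself was higher without passing the threshold in edgeR. Avp (ENSRNOG00000021229) stood at 6153 ± 1218 CPM in euhydrated and 8475 ± 928 CPM in dehydrated libraries, a log2 fold change of 0.46 ± 0.15 (SE; edgeR adjusted p = 0.080). Over the alternatives its adjusted p ran from 0.0144 to 0.338. It passed with DESeq2 (0.0144), with limma-voom (0.0200) and in edgeR without euhydrated 2 (0.0463, at a log2 fold change of 0.36), the library with the least Avp. As a share of all counts Avp took 0.620% ± 0.120 (SD, n = 5) in euhydrated and 0.839% ± 0.0921 in dehydrated libraries (exact permutation p = 0.0159, adjusted p = 0.0238 over 3 shares). Oxt (ENSRNOG00000021225), for oxytocin, had a log2 fold change of 0.18 ± 0.09 (edgeR adjusted p = 0.254), and its share was 0.302% against 0.336% (exact permutation p = 0.175). Both transcripts together took 0.922% and 1.18% of the counts (exact permutation p = 0.0159, adjusted p = 0.0238).

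**Figure D1:**
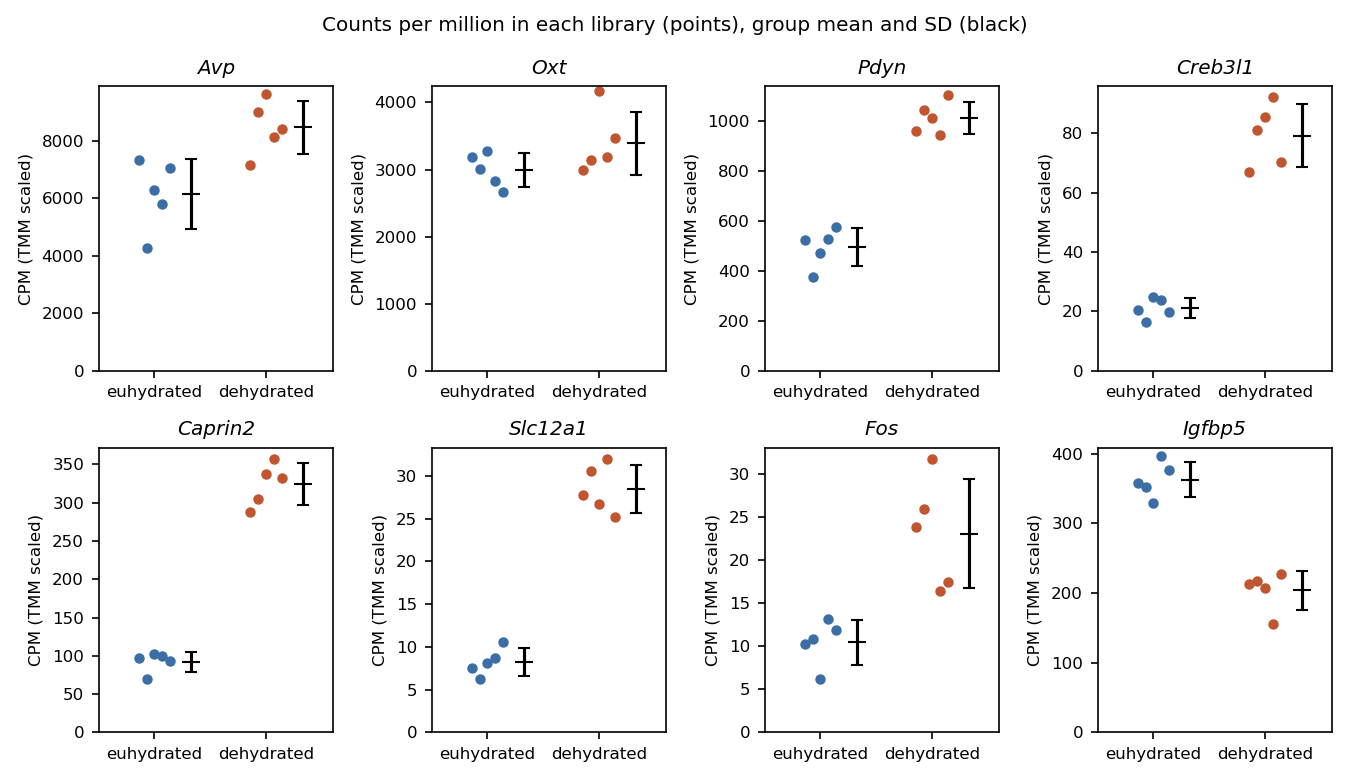
CPM after TMM scaling (y axes, from 0) of 8 genes in each of the 5 euhydrated (blue) and 5 dehydrated (orange) libraries, with the group mean and SD in black. Creb3l1, Caprin2, Slc12a1, Pdyn and Fos were higher and Igfbp5 lower in all dehydrated than in all euhydrated libraries, while Avp and Oxt overlapped.

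Across the transcriptome, 1942 of 15311 genes passed the threshold, 1192 higher and 750 lower in dehydrated samples. Most changes were small: the median fold was 1.19 among genes that rose and 1.16 among genes that fell, and 75 rose and 10 fell by more than 2-fold. When a fold above 1.5 was itself tested, 44 genes rose and 1 fell. In 10.9% of the genes tested the groups did not overlap, against 0.794% by chance. Scaling to library totals, which shifted the median log2 fold change of all genes from -0.0058 to -0.033, turned the split to 904 higher and 1173 lower. With the mean level of erythrocyte markers as a covariate, an alternative added after the data were seen, 799 genes passed, 595 higher and 204 lower. That level was itself lower in dehydrated libraries (-0.84 log2 CPM), so this covariate carries part of the group difference.

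The largest rises by the fixed rule were those of Oacyl, Tnfaip6, Dpys, Grpr, Alkal2, Procr, Creb3l1 and Giot1. Tnfaip6, for a secreted hyaluronan-binding protein, rose 8.13-fold, from 2.98 ± 0.446 to 24.3 ± 5.46 CPM (SD, n = 5; edgeR adjusted p = 8.07e-07). Dpys, for dihydropyrimidinase, rose 5.36-fold (edgeR adjusted p = 1.37e-06), and Alkal2, for a ligand of the receptor tyrosine kinase Alk, rose 4.69-fold (edgeR adjusted p = 1.84e-05). Oacyl rose 8.36-fold with a wide spread, 14.2 ± 10.5 against 118 ± 54.2 CPM (edgeR adjusted p = 0.0144), and lost its call with the oligodendrocyte marker level as a covariate (log2 fold change 3.07 against 3.06 without it, adjusted p = 0.0548, in a range of 3.69e-05 to 0.0939 over the alternatives). Grpr, for the receptor of gastrin-releasing peptide, rose 5.03-fold from a low level of 1.76 ± 0.834 CPM (edgeR adjusted p = 0.00605), and Procr, for the endothelial protein C receptor, 3.99-fold (edgeR adjusted p = 0.000137). Among other genes that rose with a symbol, a mean of at least 5 CPM and no overlap between the groups, uncharacterised loci left out, the smallest p-values belonged to Nucb1, a Golgi calcium-binding protein (1.42-fold, edgeR adjusted p = 3.08e-08), Etv5, an ETS transcription factor (1.74-fold, 6.82e-08), Atf4 (1.43-fold, 1.26e-07) and Nrsn1 (1.61-fold, 1.34e-07).

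The largest falls by the same rule were smaller than these rises. Igfbp5, for an insulin-like growth factor binding protein, was 1.78-fold lower, 363 ± 25.5 against 204 ± 28.0 CPM (SD, n = 5; edgeR adjusted p = 0.000498). Rxrg, for a retinoid X receptor, was 1.62-fold lower (edgeR adjusted p = 3.88e-05), Wfs1, for an endoplasmic reticulum membrane protein, 1.58-fold (0.00579), and Dact1 1.57-fold (0.000362). Trappc6a, Dbp, Clic6 and Mall had log2 fold changes of -0.63, -0.62, -0.59 and -0.59. Under the same conditions, the smallest p-values among other genes that fell belonged to Rpl3, a ribosomal protein (1.20-fold lower, edgeR adjusted p = 1.68e-05), Tafa5 (1.22-fold, 1.89e-05), the vesicle protein gene Rph3a (1.24-fold, 2.66e-05) and 5330417C22Rik (1.36-fold, 3.07e-05). With the erythrocyte covariate 37 of the 96 named genes past the threshold lost their calls, among them Grpr, Wfs1, Trappc6a, Dbp, Clic6 and Mall (edgeR adjusted p of 0.0521 to 0.123). Of these 37 genes 17 had a larger and 20 a smaller change than without the covariate, with a median ratio of 0.988, while the SE was larger for 36, with a median ratio of 1.36. Wfs1 went from -0.66 ± 0.12 to -0.70 ± 0.17 (SE, log2) and Clic6 from -0.59 ± 0.12 to -0.48 ± 0.17.

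Of the fixed lists, 9 were higher and 3 lower than other genes with the preset correlation, and 3 and 1 with an estimated correlation. In 14 of 100 splits of the same 10 libraries into 5 and 5, the real one included, the preset correlation gave as many lists, so the estimated correlation is printed beside each. The erythrocyte list, itself lower, is described with the other cell type markers.

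The genes of the amino acid response, many of them targets of the transcription factor Atf4, rose together. Of 31 members tested 22 rose, 1 fell and 8 did not pass; adjusted over the list alone 26 rose and 2 fell (camera adjusted p = 2.01e-19, adjusted p = 0.00216 with an estimated correlation). Aldh1l2 and Mthfd2, both enzymes of mitochondrial folate metabolism, rose 1.82- and 1.67-fold (edgeR adjusted p = 0.000250 and 3.92e-05). Trib3 rose 2.93-fold from 0.361 CPM (edgeR adjusted p = 0.00271; 0.0517 with the erythrocyte covariate, at a log2 fold change of 1.45 ± 0.40 against 1.55 ± 0.30, SE, and no higher under the other alternatives). Phgdh, for serine synthesis, fell 1.10-fold (edgeR adjusted p = 0.047), a call lost without euhydrated 2, 3 or 5 or dehydrated 1, 2, 3 or 5 (0.0712 to 0.115).

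Glucocorticoid-responsive genes also rose as a group, with 19 of 28 higher, 1 lower and 8 not past the threshold, and 21 and 1 adjusted over the list alone (camera adjusted p = 4.45e-12, adjusted p = 0.025 with an estimated correlation). Hif3a rose 3.39-fold from 1.07 CPM (edgeR adjusted p = 1.51e-05) and Sult1a1, for a sulfotransferase, 2.10-fold (0.000143). The member that fell, Nr3c2, had a log2 fold change of -0.18 (edgeR adjusted p = 0.0449), a call lost in 9 fits without 1 library. Rasd1, a Ras-family gene induced by dexamethasone, rose 1.81-fold (edgeR adjusted p = 3.52e-05), but it is a member of the immediate early list and not of this one. Nr3c1, for the glucocorticoid receptor, had a log2 fold change of -0.11 ± 0.05 (edgeR adjusted p = 0.201).

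Of 29 genes of osmotic and volume regulation 8 rose, 2 fell and 19 did not pass, with 11 and 2 adjusted over the list alone (camera adjusted p = 0.00139, adjusted p = 0.0296 with an estimated correlation). Beside Slc12a1, the betaine carrier gene Slc6a12 rose 1.59-fold (edgeR adjusted p = 0.0131, and 0.00307 to 0.0914 over the alternatives, the highest with the erythrocyte covariate, which ended the call, with a log2 fold change of 0.67 ± 0.16 (SE) without it and 0.67 ± 0.22 with it). Slc6a12 was low, at 2.09 CPM in euhydrated and 3.32 CPM in dehydrated libraries, and the groups overlapped. Slc6a6 fell from 36.6 to 31.9 CPM (log2 fold change -0.20, edgeR adjusted p = 0.0367). That call was lost in 7 fits without 1 library, and its adjusted p ran from 0.0179 to 0.0942 over the alternatives. Slc12a5, for the neuronal potassium-chloride cotransporter that keeps chloride low, fell 1.11-fold (edgeR adjusted p = 0.00593).

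Glutamate and GABA receptor genes were lower as a group: 7 of 41 fell, 3 rose and 31 did not pass, with 13 and 4 adjusted over the list alone (camera adjusted p = 0.000526, adjusted p = 0.0296 with an estimated correlation). Grm5, a metabotropic glutamate receptor, fell 1.19-fold (edgeR adjusted p = 0.00889), and Grin1, the obligatory NMDA receptor subunit, rose 1.09-fold (0.0142). Both lost their calls with the erythrocyte covariate (edgeR adjusted p = 0.0536 and 0.274, the highest over the alternatives). Grm5 went from -0.25 ± 0.06 to -0.28 ± 0.08 (SE, log2), with a wider SE and no smaller change, while Grin1 went from 0.13 ± 0.03 to 0.08 ± 0.04, a smaller change.

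In the secretory pathway, single genes passed while camera did not hold with an estimated correlation. The fry test, which sets no list against other genes, put the magnocellular peptide, granule and chaperone lists higher (fry adjusted p = 6.34e-05 for each). It also put the transport (0.00611), immediate early (0.00187) and identity (0.00454) lists higher. Of 18 magnocellular peptide and co-transmitter genes 6 rose and 0 fell (7 and 0 adjusted over the list alone, camera adjusted p = 0.000283, adjusted p = 0.0599 with an estimated correlation). Vgf, for a secreted peptide precursor, rose 3.41-fold (edgeR adjusted p = 1.82e-06) and Th, for tyrosine hydroxylase, 3.13-fold (0.00612). Crh had a log2 fold change of 0.99 ± 0.24 at 6.26 CPM in dehydrated libraries (edgeR adjusted p = 0.0203; 0.0507 without dehydrated 3 at a log2 fold change of 0.91, in a range of 0.000237 to 0.145 over the alternatives). Gal and Cck had log2 fold changes of 0.07 ± 0.19 and -0.15 ± 0.28 (edgeR adjusted p = 0.875 and 0.789). Of 19 peptide processing and granule genes 7 rose and 0 fell (9 and 2 adjusted over the list alone, camera adjusted p = 0.00174, adjusted p = 0.18 with an estimated correlation), led by Scg2 (1.96-fold), Ptprn (1.81-fold), the prohormone convertase gene Pcsk1 (1.69-fold) and the amidating enzyme gene Pam (1.55-fold), with edgeR adjusted p of 0.000328, 3.46e-07, 0.000116 and 1.94e-07.

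Of 36 endoplasmic reticulum chaperone and unfolded protein response genes 21 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 3.31e-11, adjusted p = 0.103 with an estimated correlation). The chaperone gene Hspa5 rose 1.39-fold and Pdia4 1.34-fold (edgeR adjusted p = 1.02e-06 for both). Of 41 genes of translocation and transport to the Golgi 12 rose and 1 fell (18 and 1 adjusted over the list alone, camera adjusted p = 8.9e-06, adjusted p = 0.321 with an estimated correlation), among them Tmed3 and Ssr1, by 0.48 and 0.32 on the log2 scale (edgeR adjusted p = 1.45e-05 and 0.000904). Of 37 immediate early and activity-regulated genes 15 rose and 1 fell (15 and 2 adjusted over the list alone, camera adjusted p = 1.13e-07, adjusted p = 0.226 with an estimated correlation). Fosl1 rose 10.5-fold from 0.759 CPM (edgeR adjusted p = 4.51e-08), Giot1 3.75-fold (4.76e-08), Maff 2.36-fold (3.01e-05) and Fos 2.21-fold (0.0151). Of 18 magnocellular identity regulators 6 rose and 1 fell (8 and 2 adjusted over the list alone, camera adjusted p = 0.0229, adjusted p = 0.436 with an estimated correlation, and 0.0599 without dehydrated 3 at the preset one); beside Caprin2, Cited1 rose 1.72-fold (edgeR adjusted p = 0.000392).

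**Figure D2:**
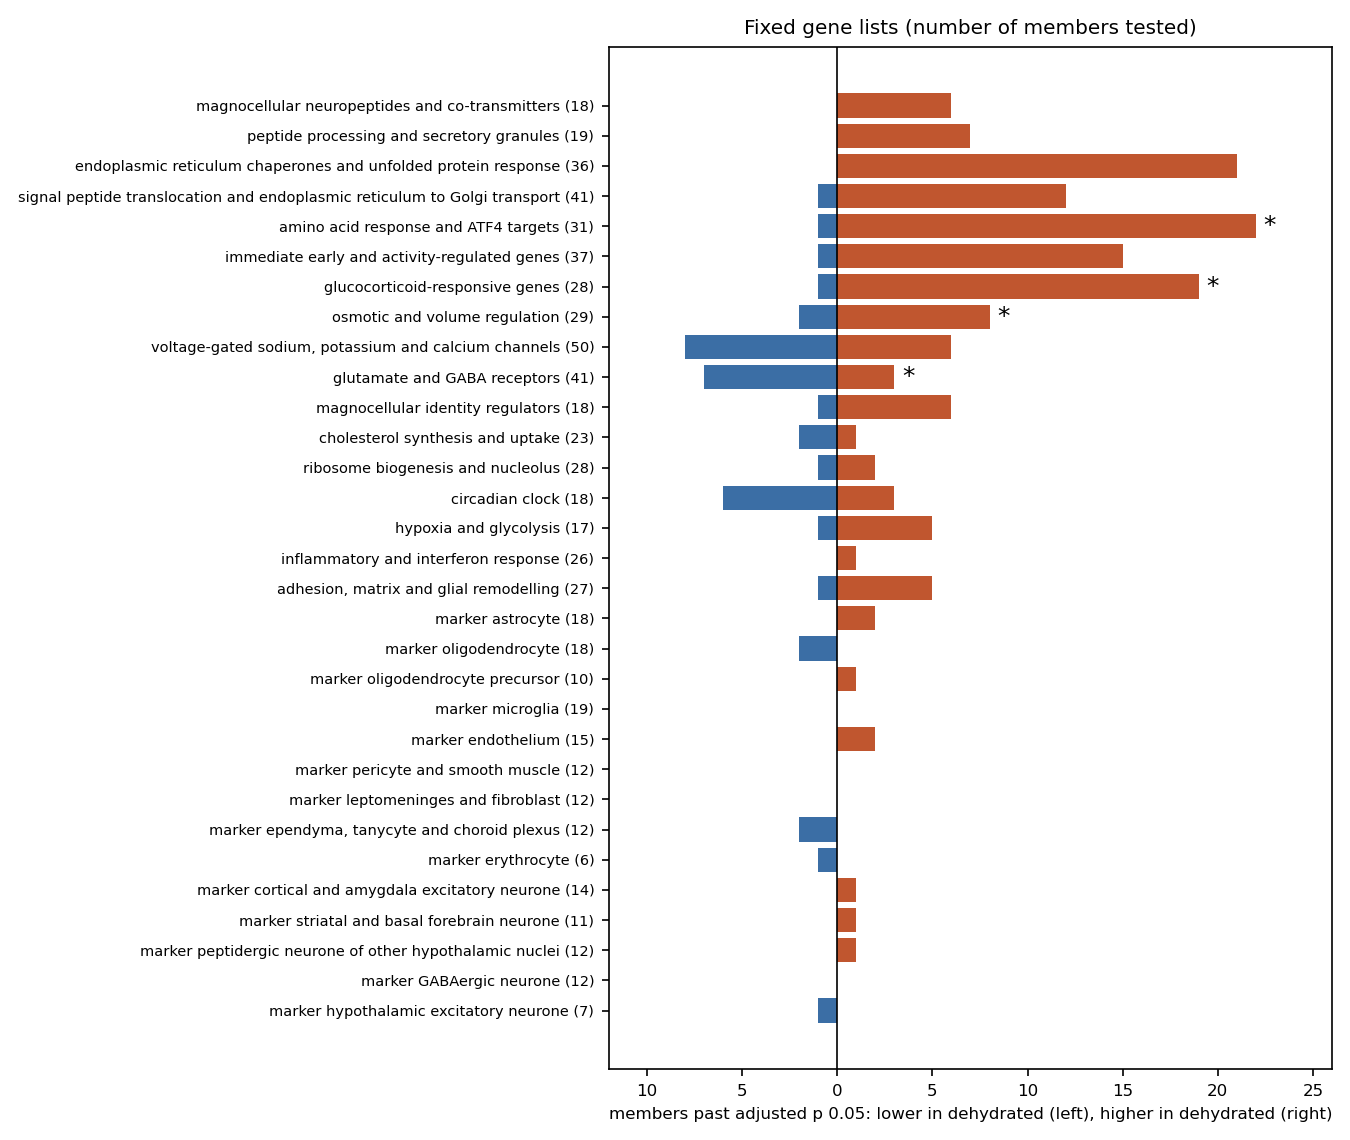
Number of members of each fixed list past the edgeR adjusted p of 0.05, with bars to the right for genes higher and to the left for genes lower in dehydrated samples, and the number of members tested in brackets. Asterisks mark the 4 lists that differ from other genes with an estimated correlation; of these, glutamate and GABA receptors are the list that is lower.

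Clock genes moved in both directions: 3 of 18 rose, 6 fell and 9 did not pass (5 and 6 adjusted over the list alone). Of all genes tested 12.7% passed. Camera looks for a net shift 1 way, which such a mix can escape, and it did not set the list apart (camera adjusted p = 0.19). The fry test put the list lower (fry adjusted p = 0.0334). Per1 rose 1.57-fold (edgeR adjusted p = 0.00467), and Nr1d1 fell 1.40-fold (0.016) and Dbp 1.54-fold (0.0235). The call of Dbp was lost without euhydrated 3, 4 or 5 or dehydrated 1, 3 or 4, at adjusted p of 0.050 to 0.0553, and the highest over all alternatives was 0.0849 with the erythrocyte covariate, where the log2 fold change went from -0.62 ± 0.14 to -0.74 ± 0.20 (SE).

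**Figure D3:**
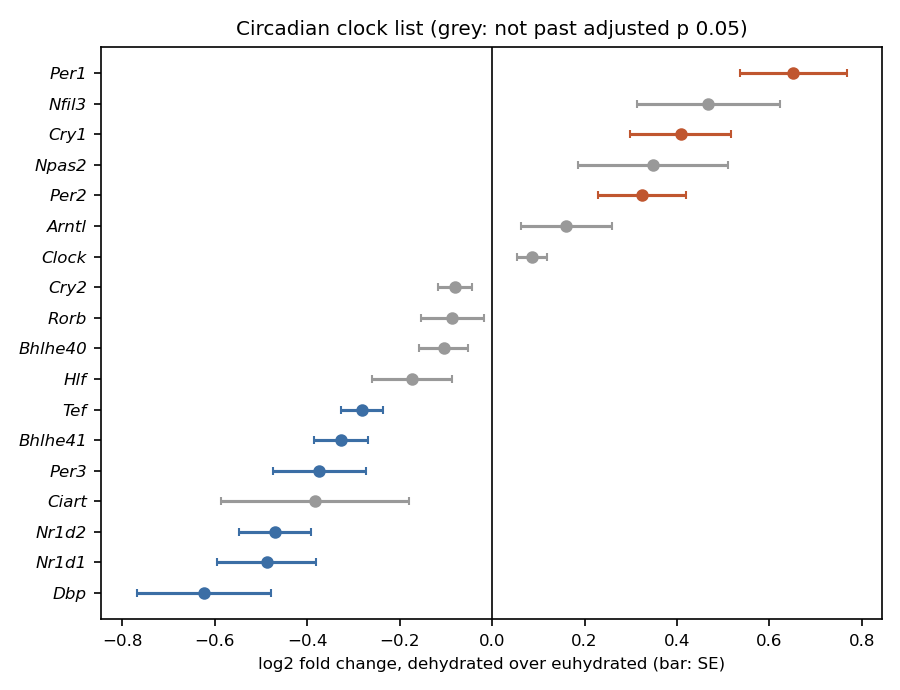
Log2 fold changes (x axis, dehydrated over euhydrated) of the 18 clock list genes tested, with bars of 1 SE. Genes higher in dehydrated samples are orange, genes lower are blue and genes not past the edgeR adjusted p of 0.05 are grey; Per1 is the highest at 0.65 and Dbp the lowest at -0.62.

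The remaining process lists did not pass camera, which can miss lists whose members move both ways, such as the channel genes. By fry, hypoxia and glycolysis (fry adjusted p = 0.000818) and ribosome biogenesis (0.0335) were higher. Of 50 voltage-gated channel genes 6 rose and 8 fell (6 and 11 adjusted over the list alone, camera adjusted p = 0.242); Kcnn3, a calcium-activated potassium channel, rose 1.44-fold and Hcn3 1.31-fold (edgeR adjusted p = 4.86e-05 and 2.54e-05), while Kcnq3 fell by 0.32 on the log2 scale (0.0159, and 0.0533 at a log2 fold change of -0.24 with the oligodendrocyte covariate, in a range of 0.00356 to 0.267 over the alternatives). Of 17 hypoxia and glycolysis genes 5 rose and 1 fell (5 and 2 adjusted over the list alone, camera adjusted p = 0.101), with Ldha, for lactate dehydrogenase, up 1.34-fold (edgeR adjusted p = 1.49e-05). Of 27 adhesion and matrix genes 5 rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.636), with Mmp9 up 2.90-fold from 0.903 CPM (edgeR adjusted p = 0.00186); the median of this list was -0.0052 and its mean 0.065, and camera put it higher. Of 23 cholesterol genes 1 rose and 2 fell (1 and 3 adjusted over the list alone, camera adjusted p = 0.489), of 28 ribosome biogenesis genes 2 rose and 1 fell (2 and 1, camera adjusted p = 0.12), and of 26 inflammatory genes 1 rose (0 adjusted over the list alone, camera adjusted p = 0.74). That gene, Stat3, had a log2 fold change of 0.11 (edgeR adjusted p = 0.0461) and lost its call without any of 8 libraries, the exceptions being euhydrated 4 and dehydrated 5 (0.0584 to 0.114).

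Punches can differ in the tissue they take, so markers of 14 other cell types were compared. No mean marker level passed the adjusted threshold. With a smallest possible p of 0.00794, 1 list alone could not pass after adjustment over 14 lists, even if the groups separated completely. The adjusted result therefore cannot show that the punches held the same mix of cells. The largest difference was in erythrocyte markers, at -0.84 log2 CPM (exact permutation p = 0.0476, adjusted p = 0.346 over 14 lists), with the lowest shares of counts in dehydrated 5 (0.0581%) and dehydrated 4 (0.0619%) and the highest in euhydrated 4 (0.208%). In the list test the erythrocyte list was lower (1 of 6 fell, also adjusted over the list alone, camera adjusted p = 0.0123, adjusted p = 0.47 with an estimated correlation). The oligodendrocyte list was lower too (2 of 18 fell, 3 adjusted over the list alone, among them Opalin by 1.19-fold, camera adjusted p = 0.0197, adjusted p = 0.707 with an estimated correlation), and lost this call without euhydrated 1, 4 or 5 or dehydrated 1 or 3 (0.0502 to 0.154). In the microglia list 0 of 19 members passed in edgeR, against 10 at an unadjusted p under 0.05, 2 in DESeq2 and 0 in limma-voom. For pericytes and smooth muscle these counts were 0 of 12, 1, 0 and 0, for leptomeninges and fibroblasts 0 of 12, 3, 1 and 1, and for GABAergic neurones 0 of 12, 2, 0 and 0. Astrocyte markers had 2 of 18 higher (2 adjusted over the list alone), among them the glutamine synthetase gene Glul (log2 fold change 0.35, edgeR adjusted p = 0.000403); the median of this list was -0.055, its mean -0.000610, and the fry test put it higher and camera lower, both far from the threshold (0.94 and 0.995). The endothelial list had 2 of 15 higher (2 adjusted over the list alone) and the ependymal and choroid plexus list 2 of 12 lower (1 higher and 2 lower adjusted over the list alone). The oligodendrocyte precursor, cortical, striatal and peptidergic lists had 1 higher each, of 10, 14, 11 and 12, also adjusted over the list alone. The median of the precursor list was 0.021 and its mean -0.0088. The peptidergic gene, Prok2, changed far more than the list, by 2.10 to 2.41 on the log2 scale over the alternatives (adjusted p = 2.55e-06 to 0.00131). It was not among the largest rises by the fixed rule, which set a minimum level and no overlap. The hypothalamic excitatory neurone list had 1 of 7 lower, also adjusted over the list alone, Foxb1 (1.70-fold; edgeR adjusted p = 0.0033).

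The authors' deposited table lists 2246 genes at an adjusted p under 0.05, 1323 higher and 923 lower in dehydrated samples. Of these, 1919 also passed in edgeR in the same direction and 0 in the opposite one, and 23 genes passed in edgeR alone. Across genes the log2 fold changes had a Pearson r of 0.9999 with those from edgeR, and their median absolute difference was 0.00259. In the authors' deposited table Avp has a log2 fold change of 0.46 with an adjusted p of 0.0149.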

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

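The counts of splits were planned before their results were seen, except that the split count with an estimated correlation was added once the one with the preset correlation was known; the tests of the 3 patterns weighed here were all chosen after the results were seen. Chance here means a chance division of these 10 libraries, each treated as a separate unit. A difference between cages or shared animals that follows the groups is not covered by it. For the number of genes past the threshold such chance can be excluded: 1 of 100 splits of the 10 libraries into 5 and 5, the real one, gave as many (1942, against 3 in the highest other split). For the 12 lists past the threshold with the preset correlation chance cannot be excluded, since 14 of 100 splits gave as many and the highest other gave 15. With an estimated correlation it can: 1 of 100 splits gave as many as the real 4, and the highest other gave 1.

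In 8 of 256 sets of 5 libraries 1 library stood far from the others, where chance alone would give about 12.8. Grpr was at 3.18 CPM in dehydrated 3, against 9.66 to 11.2 in the other dehydrated libraries. Igfbp5 was at 156 CPM in dehydrated 4 (207 to 227 in the others), Th at 165 CPM in dehydrated 2 (78.1 to 101) and Kcnq3 at 20.02 CPM in dehydrated 4 (16.4 to 17.2). Among euhydrated libraries, Pam was at 651 CPM in number 2 (736 to 755 in the others) and Col25a1 at 37.0 CPM in number 5 (29.6 to 31.2). The mean log2 CPM of cortical and amygdala markers was 2.92 in dehydrated 2 (3.56 to 3.64), and that of peptidergic neurone markers was 2.01 in euhydrated 4 (2.23 to 2.28).

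Of 19 peptide processing and granule genes 7 rose, 0 fell and 12 did not pass (9 and 2 adjusted over the list alone; list median 0.062, camera adjusted p = 0.00174, adjusted p = 0.18 with an estimated correlation), and a larger share of magnocellular tissue in the dehydrated punches could raise the 7. Oxt, made by the oxytocin neurones among the magnocellular cells, had a log2 fold change whose upper 95% limit was 0.40, below the median of 0.63 of the 7 called genes, which argues against more magnocellular tissue of both kinds as the whole cause for Pcsk1, Pam, Scg2 and Ptprn, while for the 3 called genes below that limit, Pcsk2, Scg3 and Ptprn2, it stays open. A larger share of vasopressin neurones alone would leave Oxt in place and stays open, since the upper 95% limit of Avp was 0.80, above that median and above 5 of the 7 called genes, with Scg2 (0.97) and Ptprn (0.86) the exceptions. Scaling moved the median of all genes by -0.027, far less than 0.63. A response of the neurones to water deprivation remains a hypothesis.

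Avp passed the threshold in DESeq2 and limma-voom and not in edgeR, and the edgeR result depended on euhydrated 2, the library with the least Avp. DESeq2 and limma-voom passed Avp with that library included, so leaving it out cannot show why the tools differ. Without that library the edgeR adjusted p was 0.0463, though the log2 fold change shrank from 0.46 to 0.36, and without each of the others it was 0.0698 to 0.162. Less magnocellular tissue of both kinds in that punch would lower Oxt as well, yet Oxt there was 1.01 times the mean of the other euhydrated libraries, while Avp was 0.645 and Pdyn 0.718 times. Creb3l1, Caprin2, Pcsk1, Ptprn and Pam, which rose with dehydration, were also lowest in euhydrated 2 among the euhydrated libraries (16.4, 69.9, 34.6, 703 and 651 CPM). Scg2 and Vgf, which rose too, were not: Scg2 was highest there (581 CPM) and Vgf (49.6 CPM) lay within the range of the others. A smaller share of vasopressin neurones in that punch, which also express Pdyn, would leave Oxt in place; it was not tested and stays open.

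Cytosolic ribosomal protein genes were lower in dehydrated samples in 35 of 75 cases (camera adjusted p = 4.11e-13 over 7 families, adjusted p = 0.151 with an estimated correlation). Loss of short transcripts could give such a fall, but ribosomal protein genes fell by 0.070 on the log2 scale relative to genes of respiratory chain subunits, whose mRNAs are also short (exact permutation p = 0.0238, two-sided). Under the other scalings the family median was -0.12 or lower. That could not test scaling, since both moved the median of all genes further down, from -0.0058 to -0.0071 (DESeq2 size factors) and -0.033 (library totals). A scaling factor common to all genes of a library cancels in the difference from respiratory chain genes, so it would not give the relative fall of 0.070. These genes have many pseudogenes, and reads shared with them were not tested. A change in the neurones or in the mix of cells stays open.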

How the results depend on the processing

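The block by column number and the erythrocyte covariate were chosen after seeing the data. Of 96 named genes past the threshold 55 kept their call at an adjusted p under 0.05 in every alternative fit and 73 in every fit without 1 library, and 0 turned direction. The stricter thresholds were counted over all genes only and were not applied to the named genes here. Genes past the threshold numbered 1494 to 1756 without single libraries, 1943 with DESeq2 size factors, 1941 without Avp and Oxt, 1804 without a filter, 1973 with a CPM filter, 2251 with DESeq2, 1920 with limma-voom, 1673 with the oligodendrocyte covariate and 1870 with a surrogate variable. Library totals gave 1173 lower genes. The erythrocyte covariate gave 799 genes, 595 higher and 204 lower, of which 751 were shared with the 1942. Among the named genes it ended calls mostly with a wider SE (larger in 36 of 37), while the changes of Hmgcs1 (-0.24 to -0.16) and Grin1 (0.13 to 0.08) shrank by more than 1.5 times. Slc4a1 is itself a member of the erythrocyte list, so its smaller change (-1.52 to -0.50) follows by construction. The erythrocyte level itself was lower in dehydrated libraries (-0.84 log2 CPM, exact permutation p = 0.0476). The covariate thus carries part of the group difference, which by itself widens the SE of the group effect. The lower number of genes therefore cannot show that the changes depend on blood content. Why the changes of single genes such as Hmgcs1 and Grin1 shrank was not tested. An adjusted p under 0.01 left 891 genes (658 higher, 233 lower) and a tested fold of 1.5 left 45 (44 higher, 1 lower), by construction. With an estimated correlation 3 lists were higher and 1 lower. With fry 3 lists passed that had not passed with the preset correlation, and 2 no longer did. In the simulated data 56% of genes with the smallest change were found, so small changes can be missed at this depth.

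With the labelled numbers as a replicate block 1861 genes passed, and with the column numbers 1956. The numbers were not taken to pair the samples: deviations of same-numbered libraries had correlations of -0.0682 to 0.141, and 2 of 10 libraries were best matched by their own number. With the column numbers Fos (log2 fold change 1.13, adjusted p = 0.118) and Oacyl (3.14, adjusted p = 0.0939) did not pass, at changes close to the 1.14 and 3.06 without the block.

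Reversals were seen only in results that had not passed, apart from the erythrocyte list, whose median of 0.016 with its own level as covariate follows by construction. For the others the cause was not tested. With library totals the median of the oligodendrocyte precursor list was -0.0061 and that of the peptidergic list -0.018. The peptidergic median was also -0.010 with the labelled block, -0.047 with the oligodendrocyte covariate and -0.24 with the erythrocyte covariate. The adhesion median was 0.00138 with the CPM filter and 0.019 with the erythrocyte covariate, where the cholesterol median was 0.016 and Gad2 0.014. Cck was at 0.012 with the oligodendrocyte covariate. Without single libraries list medians ran from -0.036 to 0.017 (adhesion), -0.042 to 0.013 (cholesterol), -0.053 to 0.055 (inflammatory), -0.022 to 0.056 (oligodendrocyte precursor), -0.067 to 0.056 (peptidergic) and -0.053 to 0.22 (striatal). Cck ran from -0.29 to 0.048 and Gal from -0.075 to 0.16. Marker level differences ran from -0.025 to 0.021 (astrocyte), -0.20 to 0.022 (cortical), -0.032 to 0.013 (oligodendrocyte precursor) and -0.00245 to 0.10 (striatal).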

Other observations

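The 7 gene families described here were chosen, and their tests run, after the data were seen, and so were the genes named here, so they are descriptions and hypotheses. Genes induced by ERK signalling, which include ETS transcription factors and feedback inhibitors of the pathway, rose together: 9 of 13 rose and 0 fell, with a median log2 fold change of 0.45 (camera adjusted p = 2.23e-09 over 7 families, adjusted p = 0.00913 with an estimated correlation). Etv5 rose by 0.80 ± 0.05 (SE, log2; edgeR adjusted p = 6.82e-08), Spred3 by 0.65 ± 0.07 (2.85e-05), Etv4 by 0.62 ± 0.10 (0.000602) and Spry4 by 0.58 ± 0.11 (0.00237). Alk, the receptor of the protein made from Alkal2, rose by 1.12 (edgeR adjusted p = 1.34e-07).

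Of 52 genes of receptors for peptide hormones 8 rose and 2 fell, and the family did not pass the test against other genes (camera adjusted p = 0.167, adjusted p = 0.154 with an estimated correlation; the median was 0.011 and turned to -0.016 with library totals). Besides Grpr, the genes of the secretin receptor Sctr rose by 1.52 ± 0.20 (edgeR adjusted p = 0.00013), of the cholecystokinin receptor Cckbr by 1.51 ± 0.11 (1.16e-06), of the relaxin-3 receptor Rxfp3 by 1.24 ± 0.12 (5.52e-05) and of the glucagon-like peptide receptor Glp1r by 0.96 ± 0.09 (3.24e-06). Nmur2, a neuromedin receptor gene, was at -0.86 ± 0.24 (edgeR adjusted p = 0.0278). Ptges, for a prostaglandin E synthase, rose by 1.86 ± 0.14 (edgeR adjusted p = 1.16e-06), while its family (4 of 12 rose and 1 fell) did not pass the test against other genes (camera adjusted p = 0.153, adjusted p = 0.207 with an estimated correlation).

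Proteasome subunit genes were slightly higher, with 13 of 36 rising, 0 falling and a median of 0.079 (camera adjusted p = 2.02e-07, adjusted p = 0.151 with an estimated correlation), and 6 of 36 with library totals. Genes of motile cilia were lower, with 8 of 46 falling, 2 rising and a median of -0.13 (camera adjusted p = 0.00161, adjusted p = 0.0167 with an estimated correlation), among them Dnah9 at -0.41 ± 0.07 (edgeR adjusted p = 0.00159). The fixed ependymal list, whose cells carry such cilia, had a level difference of -0.11 log2 CPM (exact permutation p = 0.397, two-sided). Respiratory chain subunits had 1 of 68 rising and 2 falling (camera adjusted p = 0.303, adjusted p = 0.799 with an estimated correlation).

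The mean log2 CPM of each family was also compared between the groups by exact two-sided permutation tests, which do not set a family against other genes and in which a few members with large changes can carry the mean. The difference was 0.41 for ERK-induced genes, 0.16 for peptide receptors, 0.075 for the proteasome, -0.11 for cilia and -0.096 for ribosomal proteins, each at p = 0.00794, the smallest these permutations can give (adjusted p = 0.0111 over 7 families). It was 0.20 for the prostaglandin family (exact permutation p = 0.0397, adjusted p = 0.0463) and -0.026 for the respiratory chain (exact permutation p = 0.365). With library totals the proteasome and prostaglandin families no longer passed (exact permutation adjusted p = 0.102 and 0.0889).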
